A study of Homo sapiens with 15 samples.

How the data were processed

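The study profiled accessible chromatin by ATAC-seq in HPAF-II cells treated with 1 µM Lgk974 or DMSO for 24 h or 48 h, with 15 libraries in 4 groups: 4 DMSO and 4 Lgk974 at 24 h, 4 DMSO and 3 Lgk974 at 48 h. Groups and replicate numbers were taken from the sample labels, which name HPAF-II for all 15 libraries; the growth protocol in the labels also describes KATO III cells. The deposited data used here were 1 narrowPeak list per library, so peaks were called per library and not on pooled samples. Per the submitters' processing notes, the steps included Trimmomatic, Bowtie2, Picard, SAMtools, bedtools, MACS2, HOMER, ChIPseeker, DiffBind and DESeq2, on hg38; their versions, order and settings are not given in the sources used here, nor is whether reads were shifted for the transposase or what was removed when the lists were cleaned. Such steps set which weak peaks enter a list and where their edges lie.

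Each peak had a score in the deposited lists, 10 times a −log10 q rounded down, a deposited fold (a ratio over background) and deposited −log10 p and −log10 q values, as the authors' peak caller gave them; the lowest −log10 q per list ran from 2.06 to 2.49. These values belong to the authors and were used only to describe, rank or filter peaks within a list, never to compare a peak between libraries. No read counts were used here, so the depth of each library is unknown and no count model was applied, nor an interval on reads (1 exact binomial interval, on a share of regions called in DMSO 24 h replicate 3, covers counting error over those regions only); a region not called may be open below the calling threshold of that library. The lists held 1413185 peaks, from 53610 to 127886 per library, of which 1138 on contigs other than chromosomes 1 to 22 and X were left out of regions (a mean of 90.0 with DMSO and 72.0 with Lgk974 at 24 h, two-sided exact p = 0.543, and 63.8 and 78.3 at 48 h, exact p = 0.371). In the list of DMSO 48 h replicate 4, 1 damaged line was read as lying on chromosome 1.

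Peaks of all libraries were merged into regions with bedtools 2.31.1 (overlap of at least 1 bp), giving 222814 regions with a median width of 395 bp, of which 35389 (15.9%) were called in all 15 libraries and 87949 (39.5%) in 1. A region was called in a library if any of its peaks overlapped it. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. No genome sequence and no transcript models were used here. Gene positions came from a table of RefSeq genes on GRCh38.p14, the same assembly as hg38, which gives the start and end of each gene without strand or exons. The planned promoter class was therefore replaced by regions within 1 kb of either end of a gene, and near regions lay farther than 1 kb and within 50 kb. Motif classes, exon and intron classes and repeat-masked sequence were planned and not analysed here.

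Group means of single values were compared within each time by two-sided exact permutation tests (70 assignments at 24 h, 35 at 48 h) and over both times by permuting labels within time (2450 assignments), so the smallest p was 0.0286 for either time and 0.000408 for both. Regions called in 3 to 12 libraries were tested in the same way on calling, with Benjamini-Hochberg adjustment at 0.05. Regions called in every library of one treatment and in none of the other were counted for the real split and for every other split of the same libraries (35 per time), and over both times for 100 drawn pairs of splits. The detection excess of a set of regions in a library was the mean of called minus the calling rate of that library over all regions called in the same number of libraries, in percentage points; this removes the effect of list length on average, but not where list length acts differently on regions of the same calling frequency. Genes were tested on whether any peak lay within 1 kb of an end.

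The 13 gene lists, written before the data were examined, were WNT beta-catenin targets, interferon-stimulated genes, nucleic acid sensing and interferon genes, antigen presentation, silencing of endogenous retroviruses, endogenous retrovirus genes, cell cycle, ribosome biogenesis and MYC targets, pancreatic epithelial and mucin genes, mesenchymal and fibroblast genes, immune cell genes, gastric and intestinal genes, and housekeeping genes. They held 370 genes, of which 364 were found, 2 of them by an older symbol. Lists share some genes and many regions. The genes named were fixed by rule: among regions called in all libraries of one treatment and none of the other, in each direction the 10 with the largest same-direction difference at both times, ties broken by the distance to the nearest protein-coding gene end; from each list up to 5 genes with the largest difference in calling; and always AXIN2, LGR5, RNF43, ZNRF3, NKD1, NOTUM, MYC, IFIT1, IFIT2, IFIT3, ISG15, MX1, OAS1, IRF1, IRF7, IRF9, RIGI, IFIH1, SETDB1, TRIM28 and DNMT1. The text prints a selection of the list genes, and some genes that the rule names are not reported here.

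As a possible trace of depth, the step was sought in each list whose whole multiples hold the largest share of the deposited fold values, within 0.05 of a step; chance puts 10% of peaks on a step, and a larger step would go with fewer reads.

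The tests were run on simulated data first. There 200 regions were planted as called in nearly every library of one treatment and nearly none of the other. Among 64721 regions simulated as all deposited peaks, 100% of those planted had p under 0.05 and 0% passed the adjusted threshold. The adjusted test of single regions thus could not call that many nearly separated regions. Of unplanted regions 1.41% had p under 0.05. With equal numbers (26417 regions) the shares were 99.5%, 0% and 2.59%. Of simulated unchanged lists of 60 regions, 7.5% (all deposited peaks) and 8.5% (equal numbers) had p under 0.05, above the nominal share. Of lists with a planted change of 15 percentage points 99% and 98% did, with a median recovered change of 14.0 and 14.4. Those planted lists held only regions called in a middle number of libraries, with calls drawn independently. Many regions of the gene lists were called in all 15 libraries, so these shares do not give the power for them.

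Alternatives listed before the data were examined were a deposited −log10 q of at least 5, equal numbers of peaks per library (the 53610 with the highest −log10 q, the length of the shortest list), peaks covering at least 50% of a region, 501 bp windows around summits, no filter on the number of libraries, all but one library in place of all, gene ends within 3 kb, near genes within 20 kb, reference rates from regions at or away from gene ends, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were leaving out the 3 libraries that stood apart, equal numbers without them (76756 peaks per library), equal numbers without DMSO 24 h replicate 3, equal numbers with the replicate block, and the WNT list without the regions at the ends of AXIN2.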

Results

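Open chromatin was mapped by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in HPAF-II, a human pancreatic adenocarcinoma cell line. The cells received 1 µM Lgk974 or the solvent DMSO. Lgk974 inhibits porcupine, the enzyme whose lipid modification allows WNT proteins to be secreted. The comparisons ask how accessible chromatin differs in cells whose WNT signalling is inhibited, after 24 h and after 48 h. There were 4 DMSO and 4 Lgk974 libraries at 24 h, and 4 DMSO and 3 Lgk974 libraries at 48 h. Each library came as its own list of peaks in hg38 coordinates, so a region was either called or not called in a library. Read counts were not used here, so the sequencing depth of each library is unknown. Nothing in the labels states that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

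At 24 h the DMSO lists held 106105, 104822, 127886 and 76756 peaks, with a mean of 103892 ± 20959 (SD, n = 4). The Lgk974 lists of that time held 95210, 98930, 53610 and 98304, with a mean of 86514 ± 21996 (SD, n = 4). At 48 h the DMSO lists held 91915, 104877, 84856 and 86503 peaks, with a mean of 92038 ± 9075 (SD, n = 4). The Lgk974 lists held 102869, 122834 and 57708, with a mean of 94470 ± 33365 (SD, n = 3). The difference between treatments was -17379 peaks at 24 h (two-sided exact permutation test, p = 0.314) and 2433 peaks at 48 h (exact p = 0.857). Both were within the spread between libraries. The smallest p that either time allows is 0.0286. The sequence covered by peaks was 50.8 ± 7.99 Mb with DMSO and 44.6 ± 12.7 Mb with Lgk974 at 24 h (exact p = 0.514). It was 47.4 ± 6.85 and 47.4 ± 19.1 Mb at 48 h (exact p = 0.943). Over both times, regions within 1 kb of either end of a gene held 14.97 ± 1.44% of the peak summits with DMSO (n = 8) and 16.2 ± 3.28% with Lgk974 (n = 7). The difference was 1.12 percentage points (exact p = 0.425, adjusted p = 0.637, higher in 3 of 7 Lgk974 libraries than the DMSO mean). Summits elsewhere inside genes made up 42.5 ± 1.04% and 42.2 ± 1.63%. Summits between genes made up 42.5 ± 0.920% and 41.7 ± 1.72% (exact p = 0.684 inside and 0.288 between genes).

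Of the 15 libraries, 3 stood apart. DMSO 24 h replicate 3 had a mean Jaccard index of shared regions of 0.376 with the other 14 libraries, whose own means ran from 0.478 to 0.656. Of its called regions, 36.6% were found in no other library. Lgk974 24 h replicate 3 and Lgk974 48 h replicate 3 had the shortest lists and mean indices of 0.513 and 0.478.

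**Figure D1:**
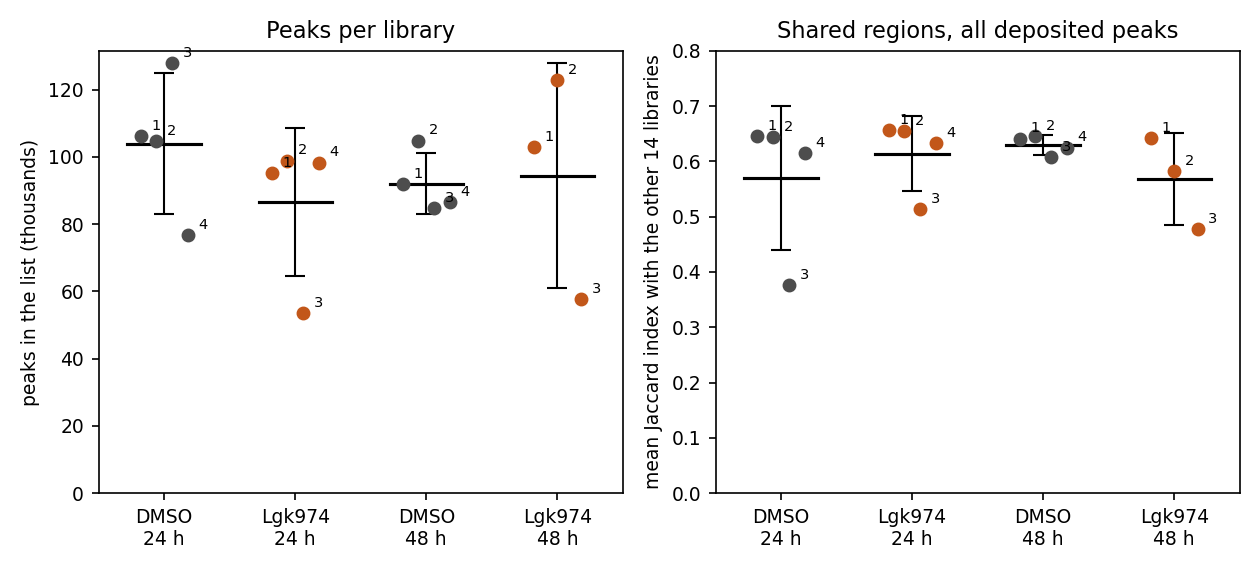
Peaks in the list of each library (left, in units of 1000 peaks) and mean Jaccard index of each library with the other 14 (right, no unit), by treatment and time; points are libraries numbered by replicate, lines are group means and bars are SDs. The treatments overlap in both panels, and DMSO 24 h replicate 3 has the longest list, 127886 peaks, and the lowest index, 0.376.

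The first question was whether single regions gained or lost accessibility with Lgk974 at both times. In all 7 Lgk974 libraries and in none of the 8 DMSO libraries, peaks were called inside PLXNB2, which encodes a semaphorin receptor (chromosome 22, 50301753 to 50302472). The same held inside ST6GALNAC4, which encodes a sialyltransferase (chromosome 9, 127915280 to 127915707). It also held within 1 kb of an end of SIK3, which encodes a salt-inducible kinase (chromosome 11, 116842917 to 116843517). The other named regions of this kind lay inside HID1 (chromosome 17, 74953119 to 74953785) and PLB1 (chromosome 2, 28624993 to 28625586), and nearest to RBMS2, ENTREP2, SPINT3 and ERGIC1. The reverse pattern, calls in 8 of 8 DMSO and 0 of 7 Lgk974 libraries, was found at an end of CARD14, which encodes a scaffold of NF-kappa-B signalling (chromosome 17, 80169751 to 80170247). It was also found inside TNFAIP8L3 (chromosome 15, 51059710 to 51060821), NINJ2 (chromosome 12, 574829 to 575539) and ACTN4, which encodes an actin cross-linking protein (chromosome 19, 38661078 to 38661558). The remaining regions lay inside ZNF385A, INTS7 and IGFL4, and nearest to ZNF503, KRT39 and XIAP, whose product inhibits caspases (chromosome X, 123846445 to 123847008). Each of these regions had an exact two-sided p of 0.000408, the smallest that the design allows over both times.

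After Benjamini-Hochberg adjustment over the 60356 regions called in 3 to 12 libraries, the exact permutation test called 0 regions (smallest adjusted p = 0.418, for regions that differed in 15 of 15 libraries). At an unadjusted p under 0.05, 1784 regions were called more often and 1857 less often with Lgk974. Together they were 6.03% of the tested regions. This near balance did not hold without the 3 libraries that stood apart, a choice made after the data were seen. Far more regions were then higher than lower. With the 53610 peaks of highest significance taken from every library, the test also called 0 of 26350 regions (smallest adjusted p = 0.0821). There 2004 were higher and 1800 lower at an unadjusted p under 0.05. Most of the fully separated regions lost calls in those equal lists. Of the 20 higher regions 6 were again called in 7 of 7 Lgk974 libraries and 9 in 2 or fewer, and of the 19 lower regions 0 were called in 8 of 8 DMSO libraries and 9 in 2 or fewer. None of the 39 was called in a library of the other treatment. The PLB1 region was called in 7 Lgk974 libraries and the SIK3 region in 6, but the PLXNB2, ST6GALNAC4, HID1, RBMS2 and ERGIC1 regions in 2 each, that of ENTREP2 in 3 and that of SPINT3 in 1. The TNFAIP8L3 region was called in 7 DMSO libraries, NINJ2 in 5, KRT39 in 4, ACTN4 in 3, INTS7 and ZNF503 in 2 each, CARD14 and ZNF385A in 1 each, and IGFL4 and XIAP in 0.

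The second question was how many regions separated the treatments completely. At 24 h, 71 regions were called in every Lgk974 and no DMSO library and 194 in every DMSO and no Lgk974 library. At 48 h there were 396 and 650. These counts moved by more than 1.5 times with single libraries. The Lgk974 count at 24 h was 823 without Lgk974 replicate 3, 163 without DMSO replicate 1 and 148 without DMSO replicate 2. The DMSO count was 699 and 795 without DMSO replicates 3 and 4, and 317, 337 and 415 without Lgk974 replicates 1, 2 and 4. At 48 h the Lgk974 count was 5439 without Lgk974 replicate 3, 688 without Lgk974 replicate 1 and 706 without DMSO replicate 2. The DMSO count was 1286 and 1407 without Lgk974 replicates 1 and 2, and 1070 without DMSO replicate 3. Regrouping the same libraries in every other way gave up to 2355 such regions at 24 h, against the real 265. It gave up to 4982 at 48 h, against the real 1046. At both times the highest split set replicates 1 and 2 against 3 and 4 of both treatments. At both times in the same direction, 20 regions were higher and 19 lower with Lgk974, and 0 went opposite ways. The higher regions numbered 80 without Lgk974 24 h replicate 3 and 32 without Lgk974 48 h replicate 3, where 3 went opposite ways. The lower regions numbered 122 without DMSO 24 h replicate 3, 30 without Lgk974 24 h replicate 4 and 29 without Lgk974 48 h replicate 2. Independent lists drawn evenly from all regions would share 0.13 and 0.57 regions. This is a low mark, since regions called in 1 or in all 15 libraries cannot separate the treatments. The 100 drawn pairs of splits gave up to 78 regions, and the pair that set replicates 1 and 2 against 3 and 4 gave 655. Of the 20 higher regions 1 lay at a gene end, 10 elsewhere inside genes and 9 between genes, and of the 19 lower regions 1, 9 and 9. Without the 3 libraries that stood apart, a choice made after the data were seen, 414 regions were higher and 125 lower at both times.

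With equal numbers of peaks the counts moved by more than 1.5 times and the order among splits turned. At 24 h, 430 regions were called in Lgk974 only and 126 in DMSO only, and at 48 h 721 and 998. No other split of the libraries gave more than 396 at 24 h or 956 at 48 h. At both times 96 regions were higher, 35 lower and 1 opposite. Without DMSO 24 h replicate 3, a choice made after the data were seen, 595 and 585 regions separated the treatments at 24 h, and 127 were higher and 171 lower at both times. For the 96 higher and 35 lower regions, independent lists drawn evenly from all regions would share 3.4 and 1.4, again a low mark. Other drawn splits gave up to 45. The 96 higher regions included 1 at the end of TFF2, which encodes a trefoil peptide secreted with mucus (chromosome 21, 42350875 to 42351648). Chosen after their values were seen, regions nearest to WNT4, a WNT ligand gene (chromosome 1, 22163255 to 22164137), MUC22 (chromosome 6, 31060005 to 31060601) and GPT (chromosome 8, 144502793 to 144503653) were also called in 7 of 7 Lgk974 and 0 of 8 DMSO libraries. A region inside RUNX1, the gene of a runt-domain transcription factor (chromosome 21, 34796588 to 34797465), chosen in the same way, was called in 0 of 7 Lgk974 and 8 of 8 DMSO libraries. None of these regions separated the treatments completely at both times with all deposited peaks. A library without a call in the equal lists may still have a weaker peak there in its full list. The mean Jaccard index within treatments minus that between them was -0.00153 at 24 h and 0.0355 at 48 h with all deposited peaks. With equal numbers it was 0.0217 and 0.0497, where the highest other splits gave 0.0188 and 0.0310.

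**Figure D2:**
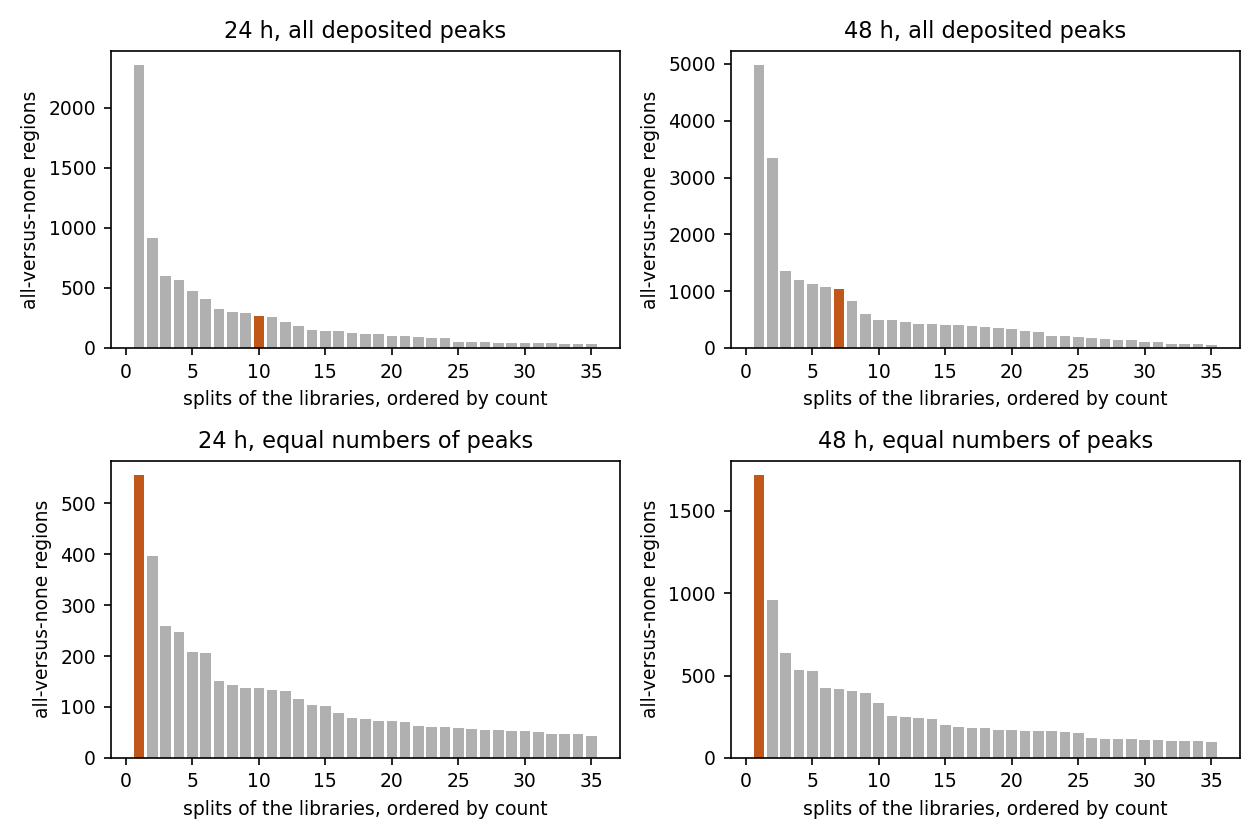
Number of regions called in every library of one group and in none of the other (vertical axis, regions) for each of the 35 ways to split the libraries of 24 h and of 48 h (horizontal axis, splits ordered by count), with all deposited peaks or equal numbers of peaks; the orange bar is the real split by treatment. The real split gives 265 and 1046 regions with all deposited peaks, below other splits, and 556 and 1719 with equal numbers, above every other split.

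Genes that beta-catenin activates downstream of WNT were examined next, since the inhibitor acts upstream of them. Their RNA was not examined here. Of the 37 with a peak at an end, 28 were called in over 12 libraries. AXIN2, a negative-feedback gene of the pathway (chromosome 17, 65528563 to 65561648), had a peak within 1 kb of an end in 7 of 8 DMSO libraries and in 0 of 7 Lgk974 libraries (exact p = 0.00204). Among the 7 genes of the list with a testable end it fell in calls, with an exact p of 0.0143 adjusted over the list alone, and was the only 1 past that threshold. Adjusted over all 1982 genes tested, its p was 0.506. With equal numbers of peaks AXIN2 had no called end in any library. The ends of RNF43 and MYC were called in 15 of 15 libraries and those of ZNRF3, which like RNF43 encodes a ubiquitin ligase that removes WNT receptors, also in 15 of 15. The end of LGR5, a receptor gene that marks intestinal stem cells, was called in 8 of 8 DMSO and 6 of 7 Lgk974 libraries (exact p = 0.429). That of NKD1 was called in 4 and 2 (exact p = 0.598) and that of NOTUM in 5 and 6 (exact p = 0.582).

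The detection excess is the calling rate of a set of regions in a library minus that of all regions called in as many libraries. Over all 61 regions at the ends of WNT target genes it was 2.75 ± 4.34 percentage points with DMSO (SD, n = 8) and -3.15 ± 2.94 with Lgk974 (SD, n = 7). It fell by 6.132 percentage points (exact p = 0.0098, p = 0.0424 adjusted over 13 lists), in 7 of 7 Lgk974 libraries below the DMSO mean. The difference was -3.85 at 24 h (exact p = 0.314) and -8.41 at 48 h (exact p = 0.0286). Over 650 regions near these genes, within 50 kb and farther than 1 kb, it was 0.698 ± 1.44 and -0.798 ± 0.380. The difference was -1.48 (exact p = 0.0192, adjusted p = 0.0831, lower in 7 of 7). Near CCND1, which encodes the G1 cyclin D1, a region 2517 bp from the gene (chromosome 11, 69638047 to 69638639) was called in 8 of 8 DMSO and 1 of 7 Lgk974 libraries. Near ID2, which encodes an inhibitor of differentiation, a region 3631 bp away (chromosome 2, 8677833 to 8678425) was called in 7 and 0 (exact p = 0.00204 each). Regions near MSX2 were called in 6 DMSO and 0 Lgk974 libraries and near PROX1 in 6 and 0. Of 17 tested regions at the ends of these genes 0 were higher and 2 lower at an unadjusted p under 0.05, both at AXIN2. Of 200 near them 7 were higher and 16 lower, and 0 passed when adjusted over the list alone. With equal numbers a region inside LGR5 (chromosome 12, 71556902 to 71557422) was called in 8 DMSO and 1 Lgk974 libraries (exact p = 0.00204). A region 2167 bp from ETS2, an ETS factor gene (chromosome 21, 38802617 to 38803016), was called in 0 DMSO and 6 Lgk974 libraries (exact p = 0.00204). Of 92 near regions tested there 5 were higher and 10 lower at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The difference of the list was then -5.23 at gene ends (exact p = 0.194, adjusted p = 0.663, lower in 6 of 7) and -2.51 near genes (exact p = 0.0339, adjusted p = 0.147, lower in 7 of 7).

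The call at WNT gene ends did not hold without the AXIN2 regions, an alternative chosen after the data were seen (-3.79, exact p = 0.0604, adjusted p = 0.214). It also ended with equal numbers, where the difference was -1.96 without DMSO 24 h replicate 3 (exact p = 0.536, adjusted p = 0.696). It ended with fixed windows around summits (-4.82), gene ends within 3 kb (-3.18), a reference of gene-end regions (-4.83, exact p = 0.0122, adjusted p = 0.0531) and without the 3 libraries that stood apart (-5.25, exact p = 0.0233, adjusted p = 0.101). It was lost without any 1 of 9 libraries. These were DMSO 24 h replicates 3 (-4.84) and 4 (-6.22), Lgk974 24 h replicates 1 (-5.66) and 2 (-5.44), DMSO 48 h replicates 3 (-6.18) and 4 (-6.37) and Lgk974 48 h replicates 1 (-6.31), 2 (-5.95) and 3 (-5.70). Adjusted p ran from 0.0177 to 0.138 over left-out libraries and from 0.0106 to 0.696 over the other alternatives.

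Interferon-stimulated genes, which infected or alarmed cells switch on, were asked about as a possible response to WNT inhibition. At their ends 42 of 50 genes were called in over 12 libraries, among them ISG15, MX1, OAS1, IRF1, IRF7 and IRF9, each in 15 of 15. Of the 5 tested genes 0 passed, either over all genes or adjusted over the list alone. IFIT1 and IFIT3, which encode RNA-binding antiviral proteins, had a called end in 8 of 8 DMSO and 6 of 7 Lgk974 libraries, and so had IFIT2. With equal numbers the end of IFIT2 was called in 3 DMSO and 6 Lgk974 libraries (exact p = 0.12). The detection excess of the 72 regions at gene ends differed by -1.24 percentage points (exact p = 0.341, adjusted p = 0.634, lower in 7 of 7 Lgk974 libraries). Near the genes, 592 regions had -0.624 ± 1.63 with DMSO (n = 8) and 0.713 ± 1.21 with Lgk974 (n = 7). The difference was 1.26 (exact p = 0.0510, adjusted p = 0.166, higher in 7 of 7). The difference near the genes was 4.43 with equal numbers of peaks (-2.08 ± 2.91 and 2.37 ± 0.964, 318 regions, exact p = 0.00612, adjusted p = 0.0796, higher in 7 of 7). It was called when peaks had to cover at least 50% of a region (2.55, adjusted p = 0.00531). Adjusted p over single left-out libraries ran from 0.0663 to 0.323.

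Single regions near interferon-stimulated genes went both ways. Of 175 tested near regions 12 were higher and 4 lower at an unadjusted p under 0.05. Of 12 at gene ends 1 was higher, at IFITM1, and 1 lower, at IFITM2. In both sets 0 passed when adjusted over the list alone. Among the 4 lower, a region 1051 bp from DTX3L and shared with PARP9 (chromosome 3, 122576254 to 122577002) was called in 8 of 8 DMSO and 2 of 7 Lgk974 libraries (exact p = 0.00612). With equal numbers, 11 of 106 near regions were higher and 0 lower, and 1 passed when adjusted over the list alone. Over all 26350 regions tested there, 14.4% had an exact p under 0.05, 2004 higher and 1800 lower. Near cell cycle genes 6 of 72 were higher and 0 lower, and near housekeeping genes 5 of 36 were higher and 2 lower. The count is thus not particular to interferon-stimulated genes. With equal numbers a region 302 bp from an end of IFIT2 (chromosome 10, 89309573 to 89310798) was called in 0 DMSO and 5 Lgk974 libraries (exact p = 0.00612, p = 0.049 adjusted over the list alone). It was not among the gene-end regions with p under 0.05 with all deposited peaks. In the same equal lists, regions near ISG20 (chromosome 15, 88648318 to 88649406) and GBP1 were called in 1 DMSO and 7 Lgk974 libraries each (exact p = 0.00204). Neither gene was among those of the list with the largest differences with all deposited peaks.

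Genes of nucleic acid sensing and interferon signalling were examined as the upstream arm of that response. RIGI and IFIH1, which encode cytoplasmic sensors of double-stranded RNA, had called ends in 15 of 15 libraries. Of the 3 testable genes 0 passed, either over all genes or adjusted over the list alone. The list differed by 1.12 percentage points at gene ends (adjusted p = 0.838, higher in 4 of 7) and 0.896 near genes (adjusted p = 0.604, higher in 4 of 7). A region near NLRP1, an inflammasome gene, was called in 7 DMSO and 0 Lgk974 libraries. A region near JAK1, a kinase gene of cytokine receptors, was called in 1 and 7 (exact p = 0.00204 each). Antigen presentation genes differed by 0.172 at gene ends (adjusted p = 0.946, higher in 3 of 7) and -1.07 near genes (adjusted p = 0.604, lower in 6 of 7). Of 2 testable genes 0 passed over all genes or adjusted over the list alone. Near CIITA, the class II transactivator gene, 1 region was called in 7 DMSO and 1 Lgk974 libraries.

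The silencing of endogenous retroviruses was asked about through the genes that carry it out and through the retroviral genes themselves. SETDB1, a histone H3 lysine methyltransferase gene, TRIM28, which encodes its recruiting corepressor, and DNMT1, which encodes the maintenance DNA methyltransferase, had called ends in 15 of 15 libraries. All 33 silencing genes with a peak at an end were called in over 12 libraries, which left 0 to test. The list differed by -1.21 percentage points at gene ends (adjusted p = 0.634, lower in 5 of 7) and 1.71 near genes (exact p = 0.166, adjusted p = 0.431, higher in 6 of 7). A region near SETDB1 was called in 2 DMSO and 6 Lgk974 libraries (exact p = 0.0306). The endogenous retrovirus genes differed by 0.498 at gene ends (adjusted p = 0.946, higher in 5 of 7) and 0.513 near genes (adjusted p = 0.895, higher in 4 of 7). Of 1 testable gene 0 passed over all genes or adjusted over the list alone. With equal numbers 4 of 14 tested regions near them passed when adjusted over the list alone. The 2 near ERV3-1 (chromosome 7, 64997951 to 64998478 and 64999309 to 65000036) rose, called in 1 DMSO and 7 Lgk974 libraries each (exact p = 0.0143 so adjusted). Those near ERVW-1, the syncytin-1 gene (6 DMSO, 0 Lgk974, p = 0.0286), and ERVFRD-1, the syncytin-2 gene (6 DMSO, 0 Lgk974, p = 0.0357), fell by the same exact test. With all deposited peaks 0 of 36 such regions passed. There 0 were higher and 1 was lower at an unadjusted p under 0.05.

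Cell cycle genes and genes of ribosome biogenesis and MYC targets, both needed for proliferation, had fewer calls at their ends with Lgk974 as sets of regions. Of 58 and 47 such regions, 35 and 33 were called in all 15 libraries and could not differ. Of 10 cell cycle regions tested 1, at MCM7, was lower at an unadjusted exact p under 0.05. Of 6 ribosome and MYC regions 3 were lower, at NOP56, LDHA and ODC1, and in both sets 0 were higher. The MCM7 region lies inside COPS6 and the NOP56 region inside IDH3B. Gene strand was not given, so it is not known whether any of these regions lay at a promoter. For cell cycle genes the detection excess of 58 regions was 2.14 ± 2.61 percentage points with DMSO (n = 8) and -2.44 ± 2.26 with Lgk974 (n = 7). It fell by 4.585 (exact p = 0.00367, adjusted p = 0.0239, lower in 7 of 7). For ribosome biogenesis and MYC targets 47 regions had 2.581 ± 3.005 and -2.95 ± 2.34. The excess fell by 5.735 (exact p = 0.00163, adjusted p = 0.0212, lower in 7 of 7). At the end of NOP56, which encodes a core protein of box C/D small nucleolar ribonucleoproteins, a region (chromosome 20, 2658468 to 2659226) was called in 6 DMSO and 0 Lgk974 libraries (exact p = 0.00612, p = 0.0367 adjusted over the list alone). A region near CDKN1A, the p21 inhibitor of cyclin-dependent kinases (chromosome 6, 36671663 to 36672277), was called in 0 DMSO and 6 Lgk974 libraries, as was a region near MCM5, a gene of the replicative helicase (exact p = 0.00204 each). Regions at the ends of MCM7 and LDHA were called in 5 DMSO and 0 Lgk974 libraries each. At gene ends 0 of 2 testable cell cycle genes passed, over all genes or adjusted over the list alone. The other 33 of 35 had an end called in over 12 libraries. No ribosome or MYC target gene was testable because 29 of 29 with a peak were called in over 12 libraries. Regions near the genes differed by 0.722 for the cell cycle (adjusted p = 0.631, higher in 4 of 7) and 0.104 for ribosome biogenesis and MYC targets (adjusted p = 0.931, higher in 3 of 7). With equal numbers they differed by 1.55 (exact p = 0.256, adjusted p = 0.332, higher in 5 of 7) and -1.97 (exact p = 0.0216, adjusted p = 0.141, lower in 5 of 7).

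Both calls turned direction with equal numbers of peaks, to 1.62 for the cell cycle (exact p = 0.321, adjusted p = 0.663, higher in 5 of 7) and 0.656 for ribosome biogenesis and MYC targets (exact p = 0.646, adjusted p = 0.764, higher in 5 of 7). Adjusted p over the alternatives ran from 0.0106 to 0.911 and from 0.0106 to 0.764. With equal numbers and without the 3 libraries that stood apart, a choice made after the data were seen, the differences were -3.89 (exact p = 0.02, adjusted p = 0.116) and -5.38 (exact p = 0.0267, adjusted p = 0.116). With the replicate number as a block the calls ended as well. The cell cycle gave -4.55 (exact sign-flip p = 0.0469, adjusted p = 0.203). Ribosome biogenesis and MYC targets gave -5.50 (exact sign-flip p = 0.0156, the smallest possible, adjusted p = 0.102). The calls also ended with fixed windows around summits (-1.24 and -5.34) and gene ends within 3 kb (-3.40, exact p = 0.0302, and -3.75, exact p = 0.00694). That of the cell cycle ended without Lgk974 24 h replicate 2 (-3.83, adjusted p = 0.0531) or Lgk974 48 h replicate 1 (-3.87, adjusted p = 0.0557).

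**Figure D3:**
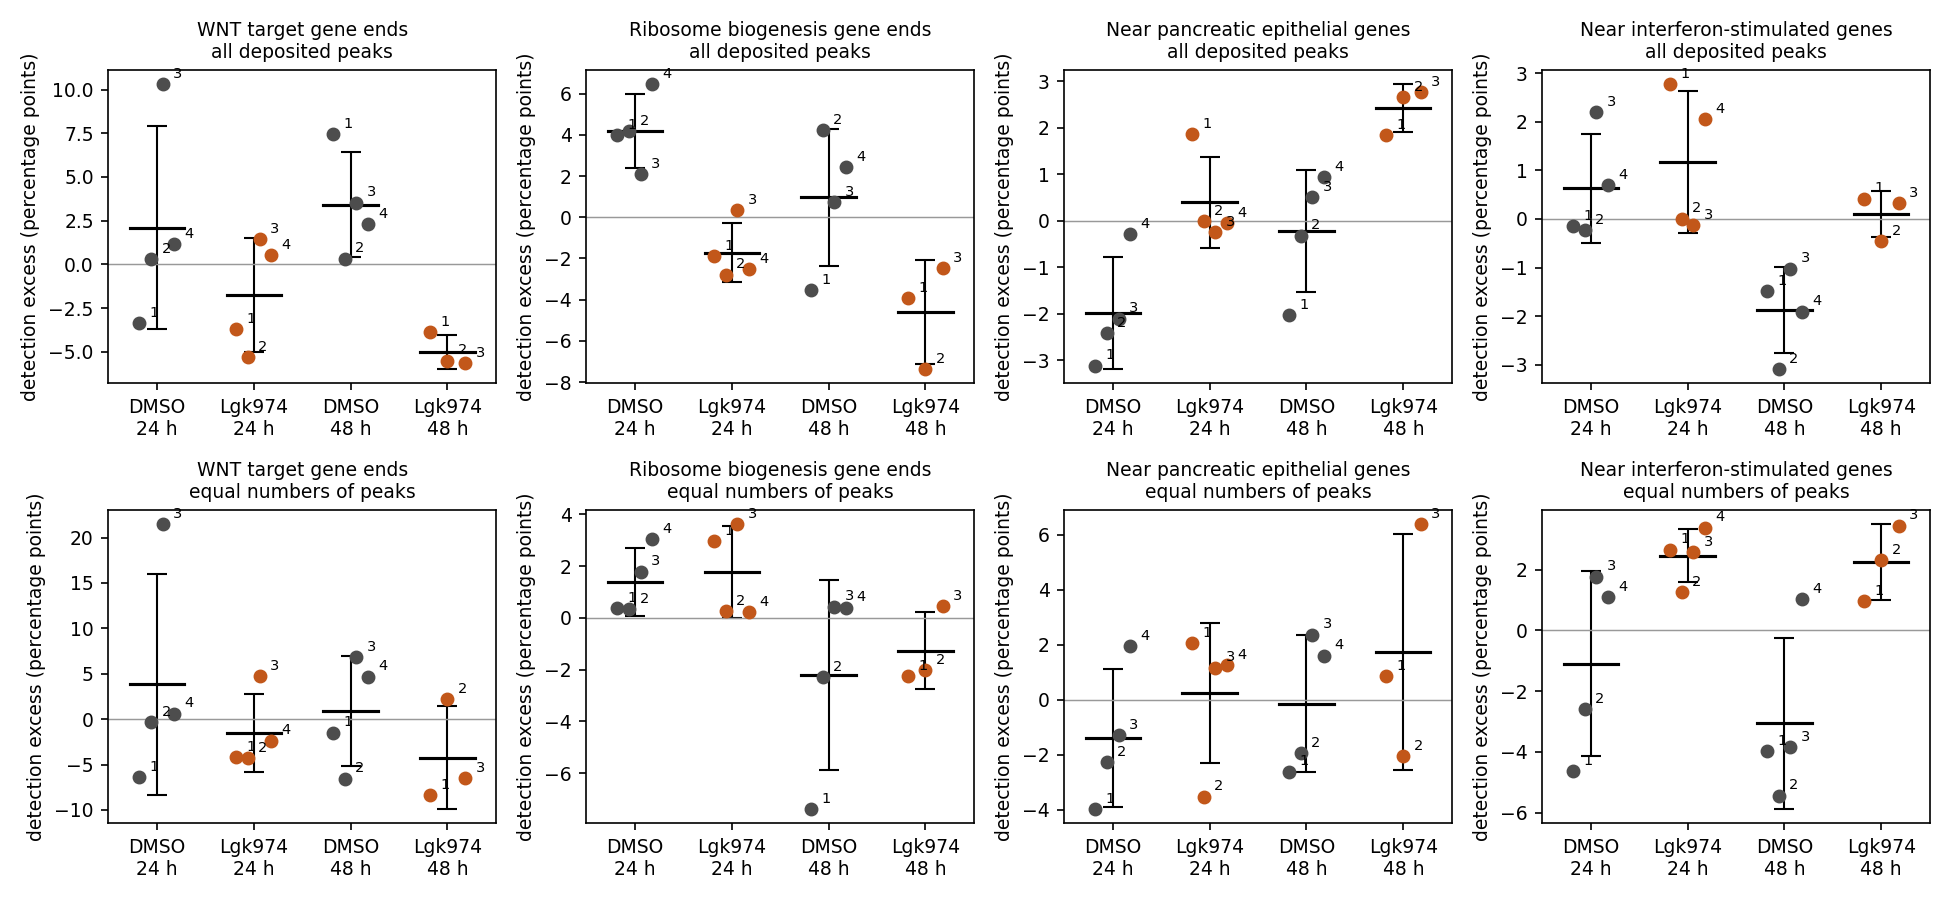
Detection excess in percentage points (vertical axis) of regions at the ends of WNT targets, at the ends of ribosome biogenesis and MYC target genes, near pancreatic epithelial and mucin genes and near interferon-stimulated genes, with all deposited peaks (top) and equal numbers of peaks (bottom); points are libraries by treatment and time, lines are means and bars are SDs. With all deposited peaks the Lgk974 minus DMSO differences are -6.13, -5.74, 2.51 and 1.26, and with equal numbers -5.23, 0.656, 1.75 and 4.43.

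Genes of the pancreatic epithelium and its mucins, which mark the ductal and secretory state of the line, gained called regions in their neighbourhood. Over 572 regions near them the detection excess was -1.10 ± 1.496 percentage points with DMSO (n = 8) and 1.26 ± 1.32 with Lgk974 (n = 7). It rose by 2.51 (exact p = 0.000816, adjusted p = 0.0106, higher in 7 of 7). A region near FOXA2, which encodes a forkhead factor of endoderm (0 DMSO, 5 Lgk974, exact p = 0.0102), and a region near SPDEF, which encodes an ETS factor of goblet cells (0 DMSO, 4 Lgk974), had more calls. A region near KRT20, a keratin gene of gastrointestinal epithelium, was called in 6 DMSO and 0 Lgk974 libraries. A region inside CDX2 and near PDX1, both homeobox genes (chromosome 13, 27965854 to 27967221), was called in 8 DMSO and 2 Lgk974 libraries (exact p = 0.0102). With equal numbers the region at the end of TFF2 passed the exact test when adjusted over the list alone (p = 0.00408). Also with equal numbers, a region near MUC5B, a gel-forming mucin gene (chromosome 11, 1219640 to 1220379), was called in 2 DMSO and 7 Lgk974 libraries (exact p = 0.0102). With all deposited peaks 5 of 149 near regions were higher and 3 lower at an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. At gene ends the list differed by 2.38 (exact p = 0.330, adjusted p = 0.634, higher in 6 of 7), and 0 of 2 testable genes passed over all genes or adjusted over the list alone.

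The call near pancreatic genes ended with equal numbers of peaks (1.75, exact p = 0.252, adjusted p = 0.332, higher in 5 of 7) and without the 3 libraries that stood apart (2.65, adjusted p = 0.108). The adjusted call was also missed, with differences about as large, with a stricter peak threshold (2.63, exact p = 0.0147, adjusted p = 0.0584), peaks covering at least 50% of a region (2.73, exact p = 0.0257, adjusted p = 0.0669) and fixed windows around summits (2.17, exact p = 0.0143, adjusted p = 0.0531). Adjusted p ran from 0.0106 to 0.402 over all alternatives. The region at SIK3 lies 5295 bp from APOA1, an apolipoprotein gene of the gastric and intestinal list. It passed the exact test there when adjusted over the list alone (p = 0.0249, and p = 0.0347 with equal numbers).

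Gastric and intestinal genes differed by 0.398 percentage points at gene ends (adjusted p = 0.946, higher in 4 of 7). Near genes they differed by 2.60 (-1.19 ± 1.67 with DMSO, n = 8, and 1.36 ± 1.99 with Lgk974, n = 7, exact p = 0.0122, adjusted p = 0.0796, higher in 7 of 7). Near CDH17, an intestinal cadherin gene, a region was called in 0 DMSO and 5 Lgk974 libraries, and near GKN2, a gastrokine gene, in 7 and 1. Mesenchymal and fibroblast genes differed by -5.43 at gene ends (exact p = 0.0657, adjusted p = 0.214, lower in 5 of 7) and 0.808 near genes (adjusted p = 0.529, higher in 4 of 7). With equal numbers the mesenchymal list differed by -9.07 at gene ends (4.37 ± 7.15 with DMSO, n = 8, and -4.99 ± 6.01 with Lgk974, n = 7, 15 regions, exact p = 0.0196, adjusted p = 0.255, lower in 7 of 7), and by -1.08 without the 3 libraries that stood apart (exact p = 0.84, adjusted p = 0.84). It was called at gene ends with all deposited peaks only without Lgk974 48 h replicate 2 (-8.76, adjusted p = 0.0454), and over all alternatives adjusted p ran from 0.0454 to 0.845. Near genes the equal-number difference was -2.74 (exact p = 0.163, adjusted p = 0.265, lower in 5 of 7). A region near ACTA2, the smooth muscle actin gene, was called in 6 DMSO and 0 Lgk974 libraries. Immune cell genes differed by -0.277 at gene ends (adjusted p = 0.946, lower in 3 of 7) and 0.876 near genes (adjusted p = 0.510, higher in 5 of 7). With equal numbers the immune list differed by 6.43 at gene ends (exact p = 0.260, adjusted p = 0.663, higher in 6 of 7) and -0.621 near genes (exact p = 0.649, adjusted p = 0.703, lower in 4 of 7). The gastric and intestinal list then differed by 3.94 (exact p = 0.28, adjusted p = 0.663, higher in 4 of 7) and 1.55 (exact p = 0.156, adjusted p = 0.265, higher in 6 of 7). A region near CD4, a co-receptor gene of T cells, was called in 7 DMSO and 0 Lgk974 libraries (exact p = 0.00204). Housekeeping genes differed by -0.375 at gene ends (adjusted p = 0.946, lower in 5 of 7) and -0.0221 near genes (adjusted p = 0.991, lower in 4 of 7). Of these genes 16 of 16 had called ends in over 12 libraries. With equal numbers the list differed by 1.82 at gene ends (exact p = 0.558, adjusted p = 0.726, higher in 5 of 7) and 2.76 near genes (exact p = 0.117, adjusted p = 0.253, higher in 6 of 7). The near value was -1.295 ± 3.34 with DMSO (n = 8) and 1.48 ± 2.51 with Lgk974 (n = 7). Without DMSO 24 h replicate 3 the near difference was 3.79 (exact p = 0.04, adjusted p = 0.173), and without the 3 libraries that stood apart the differences were 7.515 at gene ends (exact p = 0.0233, adjusted p = 0.116) and 1.56 near genes (exact p = 0.217, adjusted p = 0.402). Adjusted p over the alternatives ran from 0.116 to 1.0 at gene ends and from 0.173 to 0.984 near genes. With equal numbers, regions near the housekeeping genes GUSB (0 DMSO, 6 Lgk974) and RPLP0 (1 DMSO, 7 Lgk974) rose, with an exact p of 0.0367 for each adjusted over the list alone. In these lists 0 of 5 gastric, 6 mesenchymal and 3 immune testable gene ends passed, over all genes or adjusted over the list alone.

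Across all 19977 genes, 16254 had a peak within 1 kb of an end and 1982 could be tested by the exact permutation test. Of these 0 passed the adjusted threshold, with 31 called more often and 57 less often with Lgk974 at an unadjusted p under 0.05. With equal numbers 0 of 1558 passed, with 59 higher and 49 lower. The detection excess of all regions at gene ends differed by -0.471 percentage points between treatments (exact p = 0.643). That of regions elsewhere inside genes differed by 0.230 (exact p = 0.437) and that of regions between genes by -0.122 (exact p = 0.573).

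The last question was whether the response differed between 24 h and 48 h, which are confounded with the harvest. The change in the Lgk974 minus DMSO difference from 24 h to 48 h was tested by permuting times within treatments. It had an exact two-sided p of 0.253 for WNT gene ends, 0.352 near interferon-stimulated genes and 0.860 near pancreatic genes. Regions near cell cycle genes differed by -1.49 percentage points at 24 h and 2.93 at 48 h, a change of 4.42 (exact p = 0.0265). Regions between genes differed by 0.316 and -0.560, a change of -0.876 (exact p = 0.0176). These were the 2 smallest of 36 such tests, and about 1 in 20 falls under 0.05 by chance.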

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

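Chosen only after the result was seen were the tests of sequencing depth, a wrong label and another cell line for DMSO 24 h replicate 3, of list length and of that library for the gene lists, of the replicate number for the separation of treatments, and the counts of splits within 24 h and within 48 h; the alternatives that leave out the 3 libraries standing apart or only DMSO 24 h replicate 3 with equal numbers were added then too. Each value below lay farther from its group than Dixon's limit; 12 of 117 groups held such a value, and chance gives about 1 in 20.

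DMSO 24 h replicate 3 shared fewer regions with the other libraries, with a mean Jaccard index of 0.376 against 0.615 to 0.645 in its group, 36.6% of its regions called in no other library against 2.47 to 2.79%, and a median peak width of 327 bp against 432 to 449 bp. With only peaks of a −log10 q of at least 5 its index still lay below the lowest of the other 14 libraries (a difference of -0.0821), so weak peaks near the calling threshold are not the whole cause. Another cell line, such as KATO III, a gastric carcinoma line that the growth protocol in the labels also names, cannot be told apart: 0.0% of its 10000 strongest peaks lay in regions of its own, but so it was in all 15 libraries, and strong regions may be shared between lines; between ranks 10000 and 40000 it was 1.29% (0.0 to 0.68% in the others) and beyond 50.3% (2.27 to 23.4%). A wrong label, with an Lgk974 library in its place, cannot be told apart. DMSO 24 h replicate 3 called 24.4% of the 127 Lgk974 regions that separated the other 14 libraries (exact binomial 95% interval 17.2 to 32.8%). Lgk974 libraries called 65.8 to 92.3% of theirs (-41.4 percentage points from the lowest). It called 20.5% of the 171 DMSO regions, where other DMSO libraries called 83.3 to 100.0%, so it followed neither set. Its 2 shares did not differ detectably (Fisher's exact test, p = 0.481). As it called few regions of either set, the same limit would speak against the DMSO label too. A first test on the difference of its 2 shares (-3.94), whose limit was changed after that value was seen, decided nothing. Lower depth cannot be told apart either: Lgk974 24 h replicate 3, with the larger step between fold values, had an index higher by 0.137, but only 36.6% and 19.5% of peaks in these lists lay on such a step, and the need for 50% was added after that result; no biological explanation was tested.

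Lgk974 24 h replicate 3 had 53610 peaks (95210 to 98930 in the rest of its group), 25.5 Mb covered (50.0 to 51.4), 21.7% of summits at gene ends (14.6 to 15.2%), a mean Jaccard index of 0.513 (0.633 to 0.656), a fold step of 0.421 (0.131 to 0.149) and a detection excess at the ends of immune cell genes of -9.01 percentage points (0.256 to 1.5). The 3 libraries standing apart all carry the replicate number 3, for which the labels give no batch, and DMSO 48 h replicate 3, with an index of 0.607, did not. DMSO 24 h replicate 4 had 17.5% of summits at gene ends (13.5 to 13.9%). Near genes that silence endogenous retroviruses DMSO 48 h replicate 2 had an excess of 1.60 (-1.88 to -1.63), and near pancreatic epithelial and mucin genes Lgk974 24 h replicate 1 had 1.86 (-0.247 to -0.00509). Of 36 tests of whether the treatment difference changed between times, 2 had p under 0.05 by exact permutation: regions near cell cycle genes, with -1.49 at 24 h and 2.93 at 48 h, a change of 4.42 (p = 0.0265), and regions between genes, with 0.316 and -0.560, a change of -0.876 (p = 0.0176).

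Treatment separated the libraries more clearly with equal numbers of peaks than with all deposited peaks. With equal numbers the real split ranked first. It gave 556 regions separating the treatments at 24 h (highest other split 396) and 1719 at 48 h (highest other 956). The same held for library similarity (0.0217 against 0.0188, and 0.0497 against 0.0310). It also held for regions at both times (131 against 45) and for regions with p under 0.05 (3804 against 3025). In each case only 1 split, the real one, of 35 or of 100 drawn gave as much, a share under 0.05. For 35 splits that is the lowest share possible, and the tests reuse the same calls without adjustment. They argue against chance in this setting at that share only. With all deposited peaks it cannot be excluded for the 24 h regions (265; 10 of 35 splits as high, highest 2355), the 48 h regions (1046; 7 of 35, highest 4982), similarity (-0.00153; 13 of 35, highest 0.0595, and 0.0355; 5 of 35, highest 0.0874) or the regions with p under 0.05 (3641; 10 of 100, highest 11284), and for the regions at both times the share was under 0.05 (39; 4 of 100 drawn, highest 78; 14 of all 1225 pairs), although the pair of splits that set replicates 1 and 2 against 3 and 4 gave 655. That split, whatever the treatment, was also the highest at 24 h (2355) and then at 48 h (4982, 1 of 35 splits). It was the highest other with equal numbers (396 and 956). A structure that follows the replicate number, for which the labels give no batch, is thus a candidate source of the poor separation. So is list length, with which the count rose over the 35 splits (Spearman rho 0.338 at 24 h and 0.633 at 48 h). These sources cannot be told apart at 48 h, where every list of replicates 1 and 2 was longer than every list of replicates 3 and 4. Within replicates 1 and 2 the treatments separated 4549 regions at 24 h and 5414 at 48 h with equal numbers. The highest other of 3 splits gave 1427 and 1697. With all deposited peaks the counts were 8384 against 3035 and 9514 against 4916. Within the other replicates they were 3587 against 3054 and 15072 against 5643 with equal numbers. With all deposited peaks they were 3552 against 9260 and 27892 against 14491. At 48 h the other replicates were DMSO 3 and 4 against Lgk974 3 alone, a library that stood apart. Those 48 h counts thus cannot tell treatment from a deviation of that library. As 3 splits are too few for a share under 0.05, a treatment effect on chromatin stays open beside both sources.

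Of the gene lists, those of the cell cycle and of ribosome biogenesis and MYC targets had fewer calls at gene ends, WNT targets fewer at gene ends and, short of the adjusted threshold, near genes, and pancreatic epithelial and mucin genes more near genes. With all deposited peaks DMSO 24 h replicate 3 as the whole cause is argued against, since without it the differences were -4.37 (exact p = 0.00735), -6.34 (exact p = 0.00245), -4.84 (exact p = 0.0302), -1.49 (exact p = 0.0343) and 2.52 percentage points (exact p = 0.00245), although the adjusted call at WNT gene ends ended. A difference in list length cannot be told apart for the cell cycle and ribosome lists, whose differences turned to 1.62 and 0.656 with equal numbers but were -3.89 (exact p = 0.02) and -5.38 (exact p = 0.0267) with equal numbers and without the 3 libraries standing apart. Nor can it be told apart for near pancreatic genes (1.75, exact p = 0.252), for WNT gene ends (-5.23, exact p = 0.194, and -1.96, exact p = 0.536, without DMSO 24 h replicate 3) or near WNT targets, where equal numbers gave -2.51 (exact p = 0.0339, adjusted p = 0.147), -2.44 without the 3 libraries (exact p = 0.0333) and -1.92 without DMSO 24 h replicate 3 (exact p = 0.0596), with adjusted p from 0.108 to 0.203 over the settings with equal numbers; the limits of these tests were widened to all such settings after their values were seen. Fewer accessible regions around WNT targets upon porcupine inhibition is thus a hypothesis that these data leave open, and at gene ends it rests in part on AXIN2, without which the difference was -3.79 (adjusted p = 0.214).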

How the results depend on the processing

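Chosen only after the data were seen were the tests without the 3 libraries standing apart, with equal numbers without them or without DMSO 24 h replicate 3, with equal numbers and the replicate block, and without the AXIN2 regions; the other 11 settings and the leave-one-outs were fixed before the data were examined. Of the values that answer a comparison, 983 kept their direction and side of the threshold or stayed within their spread, 83 moved, 38 lost their call, 5 gained one and 8 reversed; of single genes and regions 2007 stayed, 29 moved and 4 gained a call. Changes of sign between values past the threshold in neither setting were not counted as reversals. Where no cause is named below, the cause was not tested. Unknown depth limits all of this, since an uncalled region may be open. Not run, for want of a genome sequence: motif classes, their summit window and GC matching, and exon, intron and repeat classes.

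Differences are in percentage points, in the order WNT, cell cycle and ribosome gene ends and near pancreatic genes. With equal numbers they were -5.23, 1.62, 0.656 (both reversed) and 1.75, with 0 lists called either way; the regions separating treatments were 430 (Lgk974 only) and 126 (DMSO only) at 24 h, 721 and 998 at 48 h, 96 higher, 35 lower and 1 opposite at both times, and similarity was 0.0217 (reversed) and 0.0497. Without DMSO 24 h replicate 3 as well: -1.96, 2.74, 0.711 (both reversed), 1.68 and 0 lists; 595 and 585, 721 and 998, 127, 171 and 1; similarity 0.0294 (reversed) and 0.0497. Equal numbers without the 3 libraries: -3.24, -3.89, -5.38, 1.87 and 0 lists; 1301 and 885, 2217 and 1547, 312, 266 and 4. Without the 3 libraries, all deposited peaks: -5.25 at WNT ends, 2.65 near pancreatic genes, 0 lists with more calls; 1170 and 717, 5437 at 48 h in Lgk974 only, 414, 125 and 6, and 2799 regions higher against 643 lower at an unadjusted p under 0.05. All but one library in place of all, a looser rule that admits more regions: 873 and 1466, 5830 and 1667, 343, 206 and 34.

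With fixed windows around summits the lists gave -4.82, -1.24, -5.34 and 2.17, and 0 lists were called. With gene ends within 3 kb the first 3 gave -3.18, -3.40 and -3.75, with 0 lists called, and with gene-end reference regions WNT ends gave -4.83. With a −log10 q of at least 5 pancreatic genes gave 2.63, with 0 lists with more calls. With peaks covering at least 50% of a region, pancreatic genes gave 2.73 and were not called, WNT (-2.04), antigen presentation (-2.28), interferon-stimulated (2.55) and gastric neighbourhoods (3.06) were, near lists with more and with fewer calls came to 2 each, and 11 regions were higher at both times. Without the AXIN2 regions WNT ends gave -3.79.

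Leaving out single libraries gave 71 to 823 Lgk974-only regions at 24 h (163, 148 and 823 without DMSO replicates 1 and 2 and Lgk974 replicate 3) and 194 to 795 DMSO-only (699 and 795 without DMSO 3 and 4, 317, 337 and 415 without Lgk974 1, 2 and 4). At 48 h it gave 396 to 5439 (706 without DMSO 2, 688 and 5439 without Lgk974 1 and 3) and 650 to 1407 (1070 without DMSO 3, 1286 and 1407 without Lgk974 1 and 2). At both times 20 to 80 were higher (80 and 32 without Lgk974 24 h and 48 h replicate 3), 19 to 122 lower (122 without DMSO 24 h 3, 30 without Lgk974 24 h 4, 29 without Lgk974 48 h 2) and 0 to 3 opposite (3 without Lgk974 48 h 3); fewer libraries make complete separation easier. WNT ends ran from -6.90 to -4.84, the call lost without 9 of 15 libraries, and WNT neighbourhoods from -1.79 to -1.25, called without DMSO 48 h replicate 2 (-1.69, adjusted p = 0.0186; range 0.0186 to 0.161). Cell cycle ends ran from -5.13 to -3.83, the call lost without Lgk974 24 h 2 or Lgk974 48 h 1. Lists with fewer calls numbered 1 to 3 at gene ends and 0 to 1 near genes, and with more calls near genes 1 to 2 (2 without Lgk974 48 h 3, when gastric neighbourhoods were called at 3.21). Mesenchymal gene ends were called without Lgk974 48 h 2 (-8.76).

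The labels do not say what same-numbered libraries share, and they were not treated as pairs because their deviations correlated at -0.032 to 0.15 (0.021 to 0.15 with equal numbers), not above 0.1 in every pair; 4 of 7 pairs had their own number as best partner, and the numbers 1 and 2 against 3 and 4 made the highest split at both times. With the replicate block over 7 pairs (smallest exact sign-flip p 0.0156) the lists gave -6.00, -4.55, -5.50 and 2.67, and 0 were called, with 140 regions higher and 199 lower at an unadjusted p under 0.05. WNT and ribosome ends and near pancreatic genes were at that smallest p, which passes the adjustment over 13 lists only beside several others at it, so these lost calls are no sign of weaker effects. Cell cycle ends were not at that smallest p (exact sign-flip p = 0.0469, adjusted p = 0.203). The block changed no other call. With equal numbers and the block they gave -4.74, 1.58, 0.975 (both reversed) and 1.94, 0 lists, with 430 and 126, 916 and 1209, 121, 35 and 1 regions.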

Other observations

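The gene families were chosen only after the results of the gene lists were seen, before their own values, and are described without a further test of cause; the test of regions far from genes was set before its result. Regions within 50 kb of the mucin genes, whose products form the mucus of ductal and gastrointestinal epithelium, had more calls with Lgk974. Over 250 regions the detection excess was -2.78 ± 2.76 percentage points with DMSO (SD, n = 8) and 3.17 ± 2.61 with Lgk974 (SD, n = 7), and the difference was 6.19 (two-sided exact permutation p = 0.000408, the smallest the design allows; adjusted p = 0.0049 over 24 families). All 7 Lgk974 and 0 of 8 DMSO libraries lay above the median of the 15, and the difference was 5.36 at 24 h and 7.02 at 48 h. It was 7.72 with equal numbers of peaks (-3.60 ± 2.95 and 4.11 ± 5.44, 134 regions, exact p = 0.00122, adjusted p = 0.0293, with 6 of 7 Lgk974 and 1 of 8 DMSO libraries above the median), 6.35 without the 3 libraries that stood apart (exact p = 0.01), 5.54 to 7.06 when single libraries and 5.35 to 7.25 when single chromosomes were left out. Of 71 single regions tested 2 were higher and 3 lower at an unadjusted p under 0.05, at MUC4 and MUC17, and with equal numbers 8 of 30 were higher and 1 lower. The examples among these were chosen after their values were seen. With equal numbers the region near MUC22 (chromosome 6, 31060005 to 31060601) was called in 0 DMSO and 7 Lgk974 libraries. With all deposited peaks a region inside MUC4, a membrane mucin gene (chromosome 3, 195809992 to 195810709), was called in 8 DMSO and 1 Lgk974 libraries (exact p = 0.00204). Several mucin genes are also in the pancreatic epithelial list, so the values are not independent.

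Regions near the KLF genes, which encode zinc-finger transcription factors, had fewer calls with Lgk974 with all deposited peaks. Over 296 regions the detection excess was 0.858 ± 0.582 with DMSO (n = 8) and -0.980 ± 0.585 with Lgk974 (n = 7). The difference was -1.87 (exact p = 0.000408, adjusted p = 0.0049, 7 of 8 DMSO and 0 of 7 Lgk974 libraries above the median). With equal numbers it was -1.70 (exact p = 0.516, adjusted p = 0.816), from -2.86 to -0.159 without single libraries, the last without DMSO 24 h replicate 3 (exact p = 0.951), and -0.678 without DMSO 48 h replicate 3. Regions near laminin genes, which encode basement membrane proteins, differed by 1.98 (272 regions, adjusted p = 0.0425, 6 of 7 Lgk974 and 1 of 8 DMSO libraries above the median), by 0.998 with equal numbers (adjusted p = 0.816; 0.153 to 1.78 without single libraries, -0.434 without the 3 that stood apart) and by 1.10 without chromosome 7 (exact p = 0.249). The other 21 families did not pass with all deposited peaks, and with equal numbers only the mucins did.

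That regions far from genes open when WNT signalling is inhibited was a hypothesis set before its result. Over 52032 regions farther than 100 kb from a protein-coding gene end the difference was -0.567 percentage points (exact p = 0.405), so no opening was detected at this precision. No single chromosome passed either, with a smallest adjusted p of 0.893 with all deposited peaks and 0.828 with equal numbers by the exact permutation test.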
